A study of Homo sapiens with 27 samples.

How the data were processed

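RNA from cultured HEK293 cells, an established human line of embryonic kidney origin, was measured on 27 single-colour Affymetrix expression arrays. Per the labels, 3 stable lines had been made by recombinase-driven insertion at a single prepared genomic site. The first line carried wild-type NOD2 (wt), the second carried the frameshift variant NOD2 L1007fsinsC, and the third carried an empty vector (mock). Cells were kept without serum for 7 h and then given muramyl dipeptide (MDP), the bacterial cell wall fragment sensed by NOD2, at 10 µg/ml for 0, 2 or 6 h, with a simultaneous harvest. Each of the 9 combinations of line and time had 3 arrays, which the labels call biological replicates 1 to 3. There was 1 line per construct, so the replicates measure variation within a line and differences between lines cannot be assigned to the construct. Total RNA was isolated on spin columns and 1 µg was converted to biotin-labelled cRNA, per the labels.

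The deposited values were linear signal intensity per probe set, which the authors had scaled per array: after trimming 2% of probe sets at each end, the mean was 750.1 on all 27 arrays. The software and version used for this step were not given in the sources used here, and no detection calls were used here. The median signal per array ranged from 165.7 to 202.7. Signal is not a molecule count, so the number of arrays per group limits the precision. Pearson's r of log2 signal was 0.953 to 0.964 between arrays of a group and 0.946 to 0.967 between arrays of different groups.

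Values were used as log2(signal + 16). Of 54675 probe sets, 62 control probe sets were left out of the tests. Gene symbols came from the platform's probe table: 41091 of the other 54613 probe sets had exactly 1 symbol, 1801 had several and 11721 had none. Of the 41091, 41037 were matched by Entrez gene number to a RefSeq gene table of the assembly GRCh38.p14, which gave current names, chromosomes and gene order. For each gene the probe set with the highest mean over all 27 arrays was used, which gave 19775 genes, 10523 of them with several probe sets. No gene was left out for low signal. Genes called brighter below are the 12256 whose mean log2 value exceeded the median of all probe sets, 7.44, and the other genes are called dim.

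All 9 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 18 residual and 1.78 prior degrees of freedom). There were 15 contrasts: 6 responses (2 h and 6 h against 0 h in each line), 6 differences between lines in these responses (interaction contrasts), and 3 differences between lines at 0 h. Tests were two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05 on the adjusted p. The median standard error of a log2 difference was 0.29 over all genes and 0.19 over brighter genes. For interactions these were 0.40 and 0.26.

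The tests, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. NOD2 was always named. In each comparison the 10 largest rises and the 10 largest falls past the threshold were named if the replicates of the groups did not overlap. Where no gene passed, the 5 genes with the smallest p were named as not passing. CXCL8, NFKBIA, TNFAIP3 and RIPK2 were given for every response. Members of a list could be named if they passed, with up to 2 that did not. Values of CXCL1 or ITGAM given where this rule does not take them were chosen after their values were seen.

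The 21 lists were NF-kB target genes, cytokines and chemokines, negative regulators of NF-kB and innate signalling, NOD2 signalling components, immediate early genes, interferon-stimulated genes, unfolded protein and amino acid stress response, cholesterol and fatty acid synthesis, FOXO and growth factor withdrawal genes, G2/M cell cycle genes, G1/S cell cycle genes, hypoxia and glycolysis genes, autophagy genes, p53 target genes, oxidative stress (NRF2) genes, heat shock genes, epithelial and antimicrobial defence genes, TGF-beta and matrix genes, HEK293 lineage markers, leukocyte markers, and fibroblast and endothelial markers. They were written from general knowledge, and some genes stand in more than 1 list. Each list was tested against all other genes with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over all 315 tests. For each list, members past the threshold were counted after adjustment over all genes, and again adjusted over the list alone.

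The pipeline was tested on simulated data made from the residuals of the arrays, with 50 genes changed at each of 4 sizes. The first version shuffled the residuals over all arrays, and 24.4% of the calls for the 2 h response of wt cells were unchanged genes, with 24.2% for the wt and mock interaction at 2 h and 21.2% for wt against mock at 0 h. After this was seen, the shuffle was restricted to arrays of 1 replicate number, since the real groups are balanced over those numbers, and no unchanged gene was called for any of the 3 comparisons. As a single draw is not representative, 15 further draws were made of each version. With the shuffle over all arrays, the mean share of unchanged genes among calls was 3.57%, 6.27% and 3.57% for these comparisons, in the same order, and the highest was 17.0%, 25.8% and 11.4%. With the restricted shuffle, the mean was 1.26%, 2.62% and 5.43% and the highest 8.33%, 18.7% and 21.7%, so single sets of calls can hold more errors than the threshold implies. In the single restricted draw on 19775 genes, the 2 h response test recovered 4, 18, 28 and 33 of 50 genes changed by 0.5, 1, 1.5 and 2 on the log2 scale. The interaction test recovered 1, 12, 21 and 33, and the 0 h test recovered 1, 17, 33 and 31. With no simulated change, 0 of 315 list tests were called in the single draw made of each version, too few draws to give an error rate.

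The alternatives fixed in advance were a replicate block, quantile normalization, median centring, pseudocounts of 1 and 64, the mean over all probe sets of a gene, leaving out dim genes, eBayes with trend and robust options, a fit to the compared groups alone, leaving out each array in turn, an estimated inter-gene correlation, and camera on ranks. Spiked-in control transcripts and principal components placed the 9 replicate 1 arrays apart from the other 18, in every group alike. Replicate 1 was therefore treated as a hybridization batch, an assignment made after seeing the data. A fit with that batch as a block and a fit to replicates 2 and 3 alone were added after seeing the data. Replicate 1 has 1 array per group, so the fit of 9 groups cannot be made on it alone. Differences between lines were tested in it with a model of line plus time, also added after seeing the data, which leaves 4 residual degrees of freedom and averages over the 3 times. Fits without genes of chromosomes with shifted medians, the contrast of 6 h against 2 h in wt cells, and the line differences at 2 h and 6 h were also chosen after seeing the data. The 27 columns of the value table were all used.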

Results

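Gene expression was measured in 3 HEK293 lines that differed in the construct inserted at a prepared genomic site: wild-type NOD2 (wt), the frameshift variant NOD2 L1007fsinsC, or an empty vector (mock). NOD2 is an intracellular receptor that activates NF-kB when it senses MDP, and the L1007fsinsC variant lacks the end of the protein. Each line was sampled at 0, 2 and 6 h of MDP with 3 arrays per group, 27 in all, and the median array signal ranged from 165.7 to 202.7. The comparisons ask which genes respond to MDP in each line, whether the responses differ between lines, and how the lines differ before MDP. Signals are given as mean ± SD (n = 3), and log2 differences with their standard error (SE) from limma over 19775 genes. The first principal component of the brighter genes held 21.2% of the variance and parted the wt line (scores -26.3 to -23.3) from the other lines (10.0 to 14.4). The second held 15.1% and parted replicate 1 of every group (17.6 to 23.6) from replicates 2 and 3 (-16.2 to -5.36).

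The NOD2 probe set gave low signal in every group. Before MDP it stood at 61.6 ± 30.8 in wt cells, 14.1 ± 3.46 in L1007fsinsC cells and 26.4 ± 27.6 in mock cells. None of the differences between lines passed, with log2 differences of 0.98 for wt against mock (adjusted p = 0.593), -0.30 for L1007fsinsC against mock (adjusted p = 0.988) and 1.28 for wt against L1007fsinsC (adjusted p = 0.408). At 2 h and 6 h the signal was 39.9 ± 58.6 and 94.0 ± 25.6 in wt cells, 60.4 ± 30.1 and 36.5 ± 45.9 in L1007fsinsC cells, and 45.7 ± 46.2 and 22.7 ± 17.2 in mock cells. Whether this probe set covers the inserted sequence is not given in the sources used here, so these values do not show how much construct was expressed.

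In wt cells, 2 h of MDP raised a small set of inflammatory genes. CXCL8, which encodes the neutrophil-attracting chemokine interleukin-8, rose 9.14-fold from 311.9 ± 52.0 to 2963 ± 203 (log2 3.19, SE 0.33, adjusted p = 6.26e-05), and its other probe set gave 3.76 (adjusted p = 0.0294 over all probe sets). CXCL1, a related chemokine, rose 6.31-fold from 150.0 ± 39.8 to 1022 ± 183 (log2 2.66, SE 0.34, adjusted p = 0.000617). TNFAIP3, which encodes the NF-kB inhibitor A20, rose 3.15-fold from 680.9 ± 128 to 2175 ± 325 (log2 1.66, SE 0.16, adjusted p = 3.05e-05), and its other probe set gave 1.21 (adjusted p = 0.59). NFKBIA, which encodes the inhibitor IkB-alpha, rose 3.02-fold from 1981 ± 372 to 5996 ± 928 (log2 1.60, SE 0.21, adjusted p = 0.00126). IER3, an early response gene that affects cell survival, rose 2.47-fold from 2926 ± 505 to 7286 ± 1416 (log2 1.31, SE 0.17, adjusted p = 0.000617).

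The sixth gene was ITGAM, which encodes an integrin chain of myeloid cells. It rose 3.27-fold from 65.2 ± 22.9 to 242.7 ± 3.02 (log2 1.71, SE 0.20, adjusted p = 0.00027). The 0 h mean lies below the median signal of every array, so this size depends on the offset, with log2 values of 1.94 and 1.26 for pseudocounts of 1 and 64. The gene lies on chromosome 16, and its other probe set gave -0.41 at a mean signal of 64.4. With the mean over all probe sets of a gene, ITGAM (0.65) and NFKBIA (1.13) no longer passed. Leaving out dim genes removed CXCL1 and ITGAM from the test, and 4 genes passed. RIPK2, which encodes the kinase downstream of NOD2, gave -0.10 (SE 0.15). No gene fell, and 633 genes (3.20%) had an unadjusted p under 0.05. Over all responses and interactions this share was 2.83% to 3.93%, below that expected at this threshold with no change. Such counts therefore do not show responses beyond the called genes. The count of 6 was 7 with the hybridization batch as a block and 11 with replicates 2 and 3 alone, both including these 6 genes. JUN, a transcription factor gene of the immediate early response, was the gene added by the block and 1 of the 5 added with replicates 2 and 3 alone. It was 11 without wt 2 h replicate 1 and 1 when the fit held the compared groups alone.

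**Figure D1:**
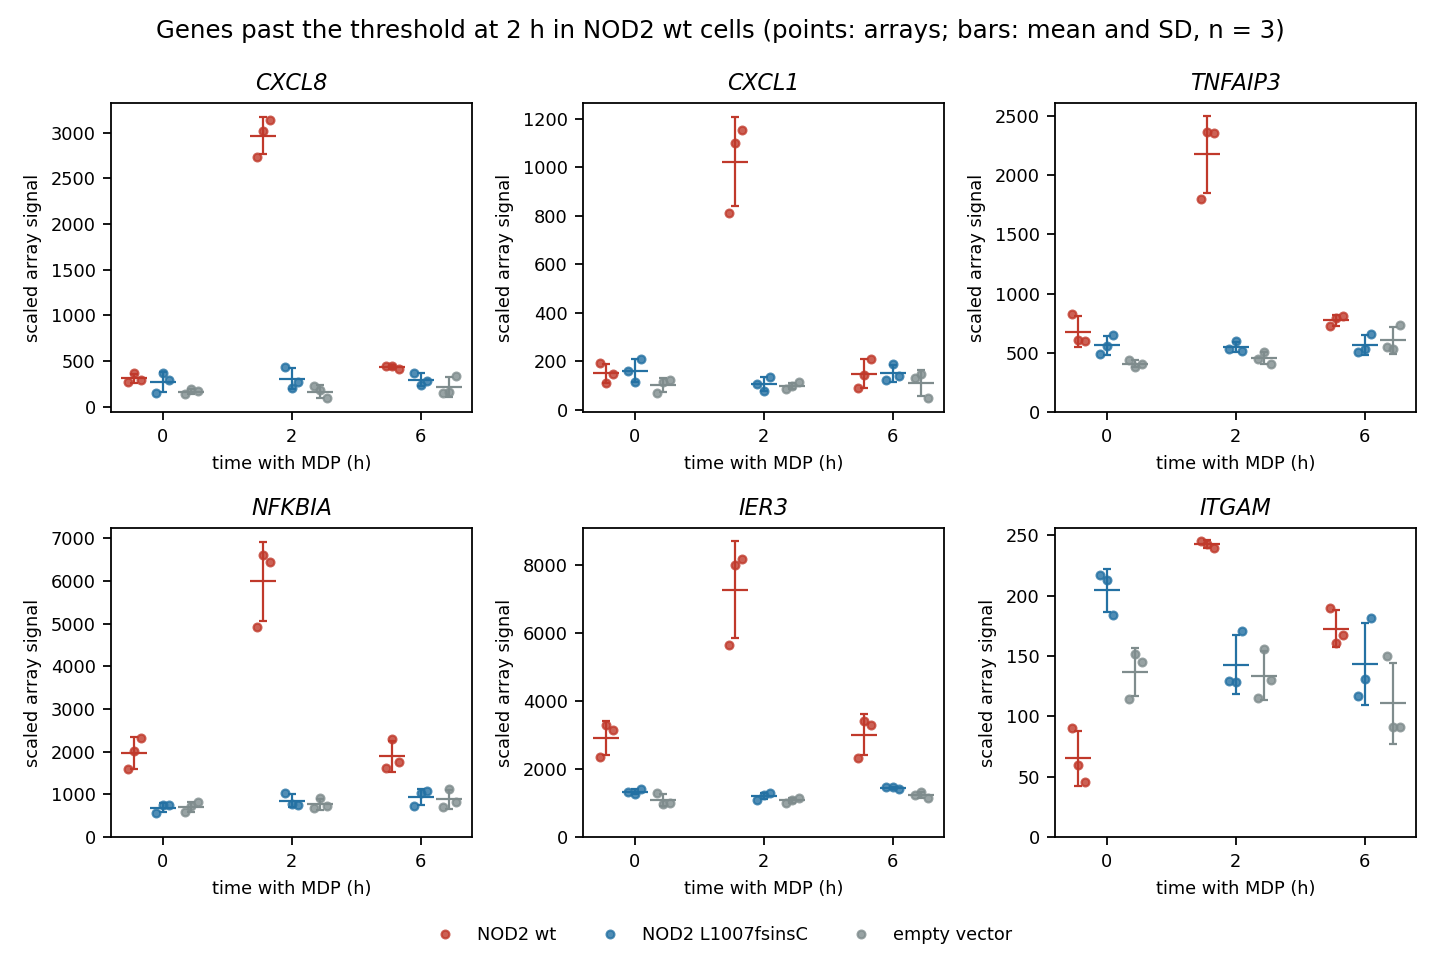
Scaled array signal of the 6 genes past the threshold at 2 h in wt cells, against hours of MDP in the 3 lines; points are arrays and bars are mean and SD (n = 3). CXCL8 went from 311.9 to 2963 in wt cells at 2 h, and its 2 h changes in the L1007fsinsC and mock lines did not pass.

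NF-kB target genes rose as a group at 2 h in wt cells: 3 of 23 measured members passed (TNFAIP3, NFKBIA and IER3), 18 of 23 had values above 0, and 7 rose when adjusted over the list alone, which added REL, NFKBIZ, CD83 and PTGS2 (camera adjusted p = 7.04e-10). Most members also lay above 0 at 2 h in L1007fsinsC cells, where the list was not called. The count of members above 0 therefore does not by itself show a response of the group. Of 28 cytokines and chemokines 2 rose, CXCL8 and CXCL1, and 4 did when adjusted over the list alone (camera adjusted p = 3.7e-06). The added chemokine genes CXCL2 and CXCL3 gave 2.27 (SE 0.70, adjusted p = 0.978 over all genes) and 1.82 (SE 0.52, adjusted p = 0.838). Of 24 negative regulators of NF-kB and innate signalling 2 rose, TNFAIP3 and NFKBIA, and 4 did when adjusted over the list alone, with DUSP1 and ATF3 added (camera adjusted p = 0.000408). That list gave an adjusted p = 0.081 with replicates 2 and 3 alone. Of 32 immediate early genes, which respond to many stimuli without new protein synthesis, 1 rose (IER3) and 4 did when adjusted over the list alone, with JUN, ATF3 and DUSP1 added (camera adjusted p = 0.00109). Over all genes JUN, which passed in those fits, gave 0.87 (adjusted p = 0.838) and ATF3 gave 0.69 (adjusted p = 0.524). All 4 list calls held with an estimated correlation. With camera on ranks only that of NF-kB target genes held (adjusted p = 0.0363), and cytokines and chemokines gave an adjusted p = 0.0633, negative regulators 0.185 and immediate early genes 0.0854.

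**Figure D2:**
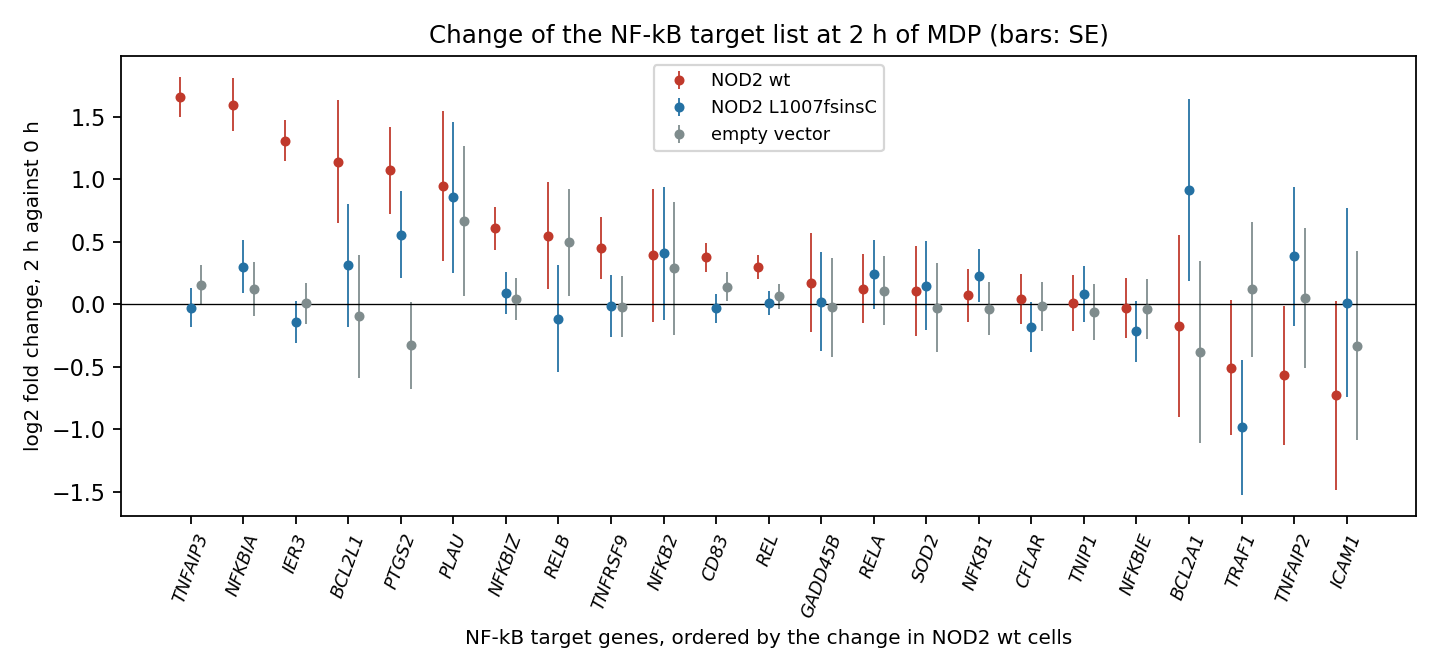
Log2 fold change at 2 h against 0 h for the 23 measured NF-kB target genes in the 3 lines, ordered by the change in wt cells; bars are SE. TNFAIP3, NFKBIA and IER3 passed in wt cells, at 1.66, 1.60 and 1.31, and no member passed in the other lines.

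By 6 h no gene passed in wt cells. CXCL8 stood at 0.47 against 0 h, TNFAIP3 at 0.20, NFKBIA at -0.06, RIPK2 at 0.03 and ITGAM at 1.25 (2.38-fold, adjusted p = 0.0796), and limma called 0 genes, with 735 at an unadjusted p under 0.05. In the contrast of 6 h against 2 h, chosen after seeing the data, CXCL8 (-2.72, adjusted p = 0.000703), CXCL1 (-2.71, adjusted p = 0.000703), NFKBIA (-1.66, adjusted p = 0.000975), TNFAIP3 (-1.46, adjusted p = 0.000252) and IER3 (-1.27, adjusted p = 0.000975) fell. ITGAM gave -0.46 there (adjusted p = 1). NF-kB target genes as a group were still higher than at 0 h (camera adjusted p = 0.00413), but not with an estimated correlation (adjusted p = 0.1), while the call held on ranks (adjusted p = 0.0493). None of the 23 members passed over all genes, and 1 rose when adjusted over the list alone, TNFRSF9, a receptor of activated lymphocytes (1.03, adjusted p = 0.609 over all genes).

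The 5 genes with the smallest p at 6 h in wt cells, none passing, were ITGAM (1.25, adjusted p = 0.0796), PROX2 (2.12, adjusted p = 0.145), APOA5 (2.25, adjusted p = 0.308), CPXCR1 (1.42, adjusted p = 0.342) and SGPP2 (0.49, adjusted p = 0.342). SGPP2, a phosphatase of sphingosine-1-phosphate, went from 1809 ± 197 to 2546 ± 115. The count of 0 was 0 with the batch block and 2 with replicates 2 and 3 alone. It was 1 without wt 0 h replicate 1, wt 0 h replicate 2 or wt 6 h replicate 3, and 2 with a pseudocount of 1, when ITGAM passed at 1.44.

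In L1007fsinsC cells no gene passed at either time of MDP. At 2 h CXCL8 gave 0.18, NFKBIA 0.30, TNFAIP3 -0.03 and RIPK2 0.07, and at 6 h these were 0.17, 0.44, 0.01 and 0.03. The smallest p at 2 h belonged to PURPL, a noncoding RNA regulated by p53 (-1.57, adjusted p = 0.109), followed by LOC101929538 (-1.82, adjusted p = 0.864), APELA (-1.20), GARIN3 (1.90) and CYP4A11 (1.75), each with an adjusted p of 1. At 6 h they were LOC101929538 (-1.94) and CYP4A11 (2.10), a fatty acid hydroxylase, both with an adjusted p of 0.67, then ZCWPW1 (1.29), the interferon gene IFNL1 (1.32) and FGF3 (1.54), each with an adjusted p of 1. None of the 21 lists was called at either time. With limma, 560 genes at 2 h and 685 at 6 h had an unadjusted p under 0.05. The 2 h count was 2 without L1007fsinsC 0 h replicate 3, with CYP4A11 at 2.37, and 1 without L1007fsinsC 2 h replicate 1, with PURPL at -1.88, or without L1007fsinsC 2 h replicate 2. The 6 h count was 3 without L1007fsinsC 0 h replicate 3, 0 with the batch block and 1 with replicates 2 and 3 alone.

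In mock cells, which measure the effect of MDP and time without inserted NOD2, no gene passed either. At 2 h CXCL8 gave -0.07, NFKBIA 0.12, TNFAIP3 0.15 and RIPK2 0.19, and at 6 h these were 0.27, 0.30, 0.54 and 0.25. The smallest p at 2 h belonged to MX1, an interferon-induced antiviral gene (-2.14), MIR7-3HG (-1.38) and LINC01813 (-2.24), all with an adjusted p of 0.074, then SLC38A11 (1.97, adjusted p = 0.146) and LINC00950 (-0.99, adjusted p = 0.226). At 6 h they were HTR2C, a serotonin receptor (2.58, adjusted p = 0.0725), FAM66C (1.97, adjusted p = 0.117), SLC38A11 (2.03, adjusted p = 0.133), and FAM99B (-2.24) and ESRRG (-1.90), both with an adjusted p of 0.161. None of the 21 lists was called. With limma, 753 genes at 2 h and 777 at 6 h had an unadjusted p under 0.05. The 2 h count was 1 with the batch block (MIR7-3HG), 0 with replicates 2 and 3 alone, 3 with a pseudocount of 1 (MX1, MIR7-3HG and LINC01813), 1 without mock 0 h replicate 1 or mock 2 h replicate 2, 2 without mock 0 h replicate 2 (SLC38A11 at 2.36), and 5 without mock 2 h replicate 3 (MIR7-3HG at -1.52). The 6 h count was 1 with the batch block, quantile normalization, median centring or a pseudocount of 1 (HTR2C in each), 0 with replicates 2 and 3 alone, 1 without mock 0 h replicate 1 or mock 6 h replicate 3 (ESRRG at -2.40), and 2 without mock 0 h replicate 2 (SLC38A11 at 2.43).

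The 2 h response of wt cells exceeded that of mock cells for 3 genes. The difference in log2 response was 3.27 for CXCL8 (SE 0.47, adjusted p = 0.0152), 1.50 for TNFAIP3 (SE 0.22, adjusted p = 0.0152) and 1.74 for ITGAM (SE 0.28, adjusted p = 0.0326). The differences for CXCL1 (2.67, adjusted p = 0.0665), IER3 (1.30, adjusted p = 0.0674), NFKBIA (1.47, adjusted p = 0.243) and RIPK2 (-0.28, adjusted p = 1) did not pass. At an unadjusted p under 0.05 there were 688 genes. CXCL1 passed with quantile normalization and with a pseudocount of 64, and IER3 with dim genes left out and with the trend and robust options. With the batch block 5 genes passed, with IER3 and NFKBIA added, and with replicates 2 and 3 alone 0 passed, although the differences were 3.60 for CXCL8, 1.73 for TNFAIP3 and 1.97 for ITGAM. A fit to the compared groups alone also called 0.

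Single arrays decided some of these calls. The count was 0 without wt 0 h replicate 3, wt 2 h replicate 2 or wt 2 h replicate 3, where CXCL8 gave 3.23, 3.25 and 3.23. It was 1 without wt 0 h replicate 2, mock 0 h replicate 1 or mock 2 h replicate 1, and 6 without wt 2 h replicate 1. TNFAIP3 was lost without any of these except wt 2 h replicate 1, and also without mock 2 h replicate 3 (1.43), with values of 1.43 to 1.50. ITGAM was lost without any of these 8 arrays, and also without mock 0 h replicate 2 or 3, with values of 1.56 to 1.85. It was lost as well with the mean over probe sets (0.62), median centring (1.71) and the trend and robust options.

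Among the lists, NF-kB target genes responded more in wt than in mock cells at 2 h (1 of 23 past the threshold, TNFAIP3, and 3 when adjusted over the list alone, with NFKBIA and IER3 added; camera adjusted p = 6.72e-05). Negative regulators did too (1 of 24, TNFAIP3, and 4 when adjusted over the list alone; camera adjusted p = 0.000384), and both calls held with an estimated correlation. Cytokines and chemokines (1 of 28, CXCL8, and 4 when adjusted over the list alone; camera adjusted p = 0.00864) did not hold with it (adjusted p = 0.0578 with an estimated correlation), and gave an adjusted p = 0.102 with replicates 2 and 3 alone. In the list of immediate early genes 0 of 32 passed over all genes, and 4 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0104). That call was not kept with an estimated correlation (adjusted p = 0.1). Its higher members were JUNB, IER3, ATF3 and DUSP1, and the lower member was FOS (-2.28). None of these 4 list calls held on ranks (adjusted p = 0.102 for NF-kB target genes and for negative regulators, 0.468 for cytokines and chemokines and 0.124 for immediate early genes).

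The 2 h response of wt cells exceeded that of L1007fsinsC cells for 6 genes. The difference in log2 response was 3.17 for CXCL1 (SE 0.47, adjusted p = 0.0114), 3.01 for CXCL8 (SE 0.47, adjusted p = 0.0148), 2.19 for ITGAM (SE 0.28, adjusted p = 0.00298), 1.68 for TNFAIP3 (SE 0.22, adjusted p = 0.00298) and 1.45 for IER3 (SE 0.23, adjusted p = 0.0168). The sixth gene was APELA, which encodes a ligand of the apelin receptor (2.49, SE 0.39, adjusted p = 0.0151). Its signal was low throughout: 5.70 ± 4.49 at 0 h and 36.3 ± 2.58 at 2 h in wt cells, and 46.7 ± 15.3 and 10.8 ± 1.99 in L1007fsinsC cells. The means of 5.70 and 10.8 lie below the offset of 16, which sets the size of this difference (4.78 and 1.08 with pseudocounts of 1 and 64). NFKBIA (1.30, adjusted p = 0.754) and RIPK2 (-0.17) did not pass. At an unadjusted p under 0.05 there were 635 genes.

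This count was 3 when dim genes were left out, which removes CXCL1, ITGAM and APELA from the test, and 0 in a fit to the compared groups alone. It was 3 without wt 0 h replicate 1 or L1007fsinsC 2 h replicate 3, and 2 without L1007fsinsC 0 h replicate 3, wt 2 h replicate 2 or wt 2 h replicate 3. CXCL8 was lost without each of these 5 arrays and without L1007fsinsC 0 h replicate 2 (2.76 to 2.99), and CXCL1 without L1007fsinsC 0 h replicate 3, wt 2 h replicate 2 or wt 2 h replicate 3 (2.98 to 3.11) and with replicates 2 and 3 alone (3.49). IER3 was lost without these 5 and without L1007fsinsC 0 h replicate 1 or L1007fsinsC 2 h replicate 1 (1.30 to 1.50). APELA was lost without these 5, without L1007fsinsC 0 h replicate 1 (2.32 to 2.51), and with a pseudocount of 64 (1.08). ITGAM was lost with the mean over all probe sets of a gene (0.93), and ITGAM and APELA with the trend and robust options.

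NF-kB target genes responded more in wt than in L1007fsinsC cells as a group (2 of 23, TNFAIP3 and IER3, and 3 when adjusted over the list alone, with NFKBIA added; camera adjusted p = 6.72e-05). So did cytokines and chemokines (2 of 28, CXCL8 and CXCL1, and 2 when adjusted over the list alone; camera adjusted p = 0.00461) and negative regulators (1 of 24, TNFAIP3, and 2 when adjusted over the list alone; camera adjusted p = 0.000493). These 3 calls held with an estimated correlation but not on ranks (adjusted p = 0.124, 0.195 and 0.0854, in this order). With replicates 2 and 3 alone the cytokine list gave an adjusted p = 0.0827 and the negative regulators 0.0664. The list of immediate early genes was not called (1 of 32, IER3; camera adjusted p = 0.0645). It was called, as higher in wt cells, with the batch block (adjusted p = 0.0118), with replicates 2 and 3 alone (adjusted p = 0.0106) and with dim genes left out (adjusted p = 0.00241).

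No gene passed a test of difference between the responses of L1007fsinsC and mock cells, which does not show that these were equal. In the single restricted draw, the simulated wt and mock interaction test at 2 h recovered 12 of 50 genes changed by 1. At 2 h the differences were 0.26 for CXCL8, 0.18 for NFKBIA, -0.18 for TNFAIP3 and -0.11 for RIPK2, and at 6 h they were -0.10, 0.15, -0.53 and -0.22. The smallest p at 2 h belonged to PURPL (-1.85) and MIR7-3HG (1.65), both with an adjusted p of 0.613, LINC01813 (2.63, adjusted p = 0.689), NALT1 (1.34, adjusted p = 0.879) and MIR31HG (-1.13, adjusted p = 1). At 6 h they were AKAIN1 (-2.93, adjusted p = 0.172), and SCART1 (3.37), FAM66C (-2.31), HTR2C (-2.64) and FLJ37201 (-0.93), each with an adjusted p of 0.654. No list was called. By limma, 709 genes at 2 h and 673 at 6 h had an unadjusted p under 0.05. The 2 h count was 1 without mock 0 h replicate 2 or L1007fsinsC 2 h replicate 2. The 6 h count was 0 with the batch block, 5 with replicates 2 and 3 alone (AKAIN1 at -3.10 among them), 2 in a fit to the compared groups alone (AKAIN1 and SCART1) and 1 without mock 0 h replicate 2.

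At 6 h the response of wt cells did not pass a test of difference from the other lines for any gene. Against mock cells CXCL8 gave 0.20, NFKBIA -0.36, TNFAIP3 -0.34 and RIPK2 -0.22, and against L1007fsinsC cells these were 0.30, -0.50, 0.19 and 0.00. The smallest p against mock cells belonged to ITGAM (1.55), OSBP2 (-3.66), HTR2C (-2.91), PHGR1 (3.31) and the histone gene H2AC8 (1.98), all with an adjusted p of 0.317. Against L1007fsinsC cells they were ITGAM (1.74, adjusted p = 0.1), and ZNRF2P1 (3.63), ARHGAP24 (3.00), FLJ37201 (0.93) and H4C10P (3.02), each with an adjusted p of 0.662. No list was called. By limma, 677 genes against mock cells and 751 against L1007fsinsC cells had an unadjusted p under 0.05. The count against mock cells was 1 without mock 0 h replicate 2 and 1 in a fit to the compared groups alone. Against L1007fsinsC cells it was 0 with the batch block, 3 with replicates 2 and 3 alone, and 1 without wt 0 h replicate 1 or L1007fsinsC 6 h replicate 3 (ITGAM at 1.95 and 1.90), wt 0 h replicate 3 or L1007fsinsC 0 h replicate 3.

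The responses of the wt and L1007fsinsC lines shared 0 called genes, since 6 were called in wt cells at 2 h and 0 in L1007fsinsC cells. Across 19775 genes, Pearson's r between the 2 h changes of these lines was -0.00694 and Spearman's rho was -0.00180. At 6 h they were 0.00762 and -0.0201. Genes are not independent replicates, and each line had its own 0 h arrays.

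Before MDP the wt line differed from the mock line in 738 genes, 284 higher and 454 lower, and 230 of them differed at least 2-fold. SOX11, a transcription factor of the developing nervous system, was at 1441 ± 164 in wt cells and 70.6 ± 57.0 in mock cells (log2 4.27). LRRN1 (2.96), the growth factor gene BMP2 (2.85; 1114 ± 226 against 143.6 ± 48.8), the potassium channel gene KCNK2 (2.79) and the endothelin receptor gene EDNRB (2.60; 1031 ± 103 against 170.0 ± 94.4) were also higher. So were SNAI2, a transcription factor of cell migration (2.57), RAPGEFL1 (2.55), the actin-binding gene TMSB4X (2.54; 16000 ± 3398 against 2766 ± 728), the monocyte chemokine gene CCL2 (2.48) and the growth-promoting transcription factor gene MYCN (2.41).

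Lower in wt than in mock cells were SFRP2, a secreted Wnt modulator (-4.37; 11.7 ± 4.41 against 572.7 ± 173), the zinc finger gene ZNF83 (-4.13; 14.6 ± 17.9 against 485.1 ± 158) and MGST1, a membrane-bound glutathione transferase (-3.95; 312.1 ± 98.1 against 4909 ± 238). The wt means of SFRP2 and ZNF83 lie below the offset of 16, and with pseudocounts of 1 and 64 the differences were -5.51 and -3.03 for SFRP2 and -5.56 and -2.79 for ZNF83. The same holds for ZKSCAN7 (-3.20 as reported, wt mean 8.33; -4.62 and -1.89) and, among the higher genes, for KCNK2 (mock mean 13.2; 3.72 and 1.69). BOLA1 (-3.83), ZKSCAN7, PABPC4L (-3.09), MAP7D2 (-3.07), ZNF677 (-2.78), LINC01806 (-2.68) and the pseudogene DUXAP10 (-2.67) followed. The SE of the 20 genes ranged from 0.18 for MGST1 to 0.67 for RAPGEFL1 and their adjusted p from 3.52e-11 for MGST1 to 0.0372 for RAPGEFL1. Replicates of the groups did not overlap, which chance gives in 10% of genes. At an unadjusted p under 0.05 there were 2744 genes. The count of 738 was 1313 with the batch block, including all 738, and 436 with replicates 2 and 3 alone, 345 of them shared. It was 411 with the mean over probe sets, 86 in a fit to the compared groups alone, 449 without wt 0 h replicate 2, 466 without wt 0 h replicate 3 and 474 without mock 0 h replicate 3. RAPGEFL1 was lost without any single one of the 6 arrays (2.45 to 2.65), and BMP2 without wt 0 h replicate 2 (2.69), mock 0 h replicate 1 (2.80) or mock 0 h replicate 3 (2.66). With replicates 2 and 3 alone BMP2 (2.91), KCNK2 (3.00), SNAI2 (2.24), RAPGEFL1 (2.38) and MYCN (2.30) did not pass, and MYCN (0.59) did not pass with the mean over probe sets.

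**Figure D3:**
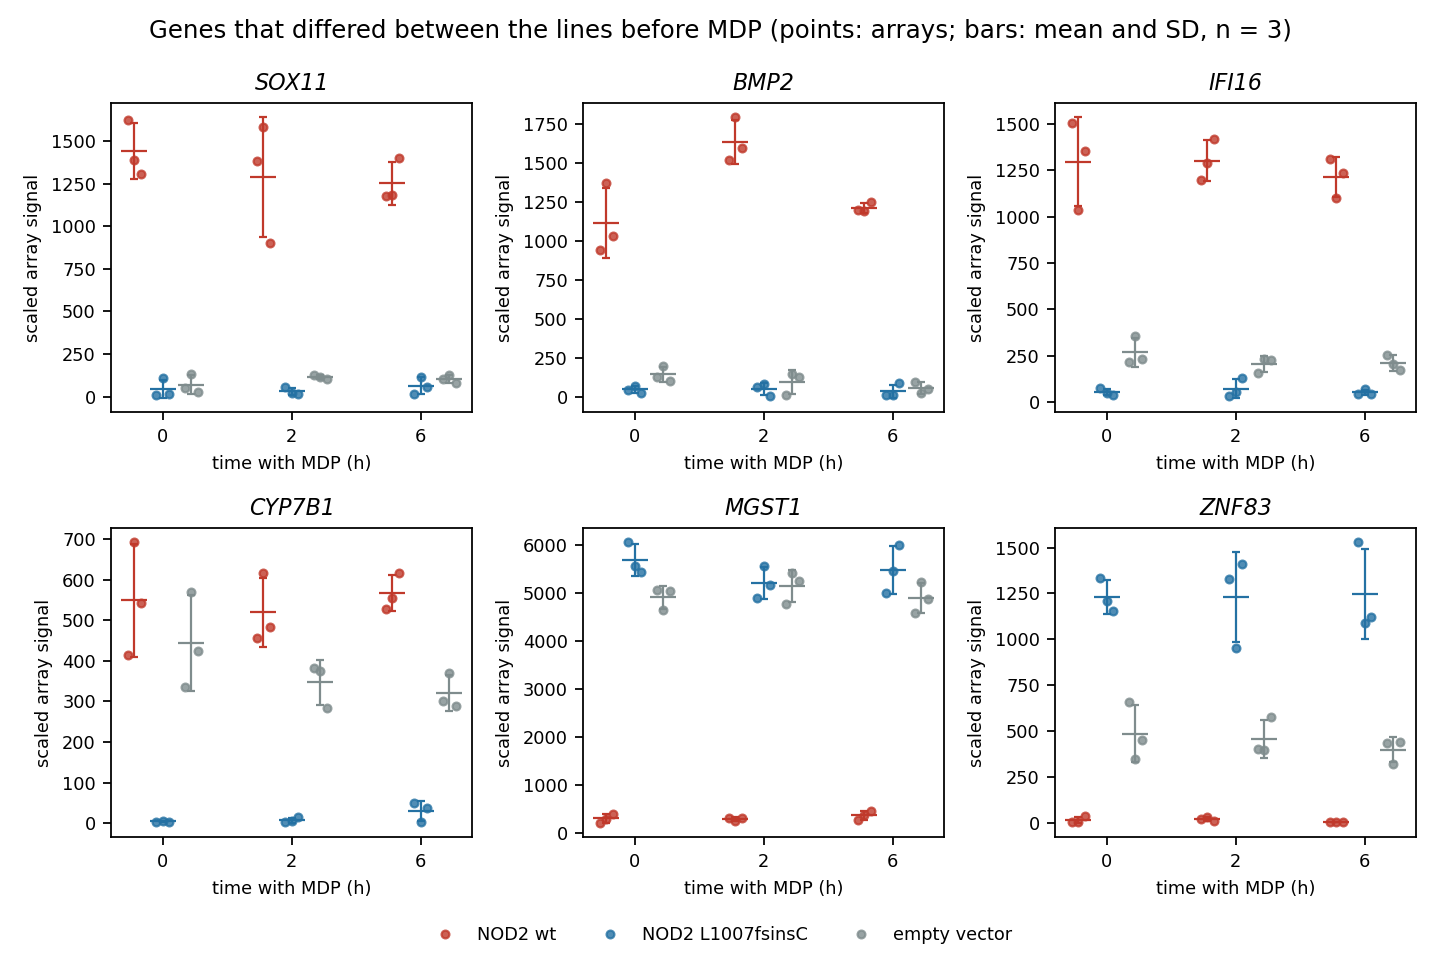
Scaled array signal of 6 genes that differed between the lines before MDP, against hours of MDP; points are arrays and bars are mean and SD (n = 3). At 0 h SOX11 was at 1441 in wt cells and 70.6 in mock cells, and MGST1 was at 312.1 and 4909.

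Several NF-kB target genes stood higher in the wt line before MDP was added. NFKBIA (1.45, adjusted p = 0.000288), IER3 (1.41, adjusted p = 2.31e-05), TNFAIP3 (0.70, adjusted p = 0.0139), TNFRSF9 (1.70, adjusted p = 0.00023) and CD83 (0.58, adjusted p = 0.00456) were higher in wt than in mock cells. These made 5 of the 23 NF-kB target genes (camera adjusted p = 0.00109; adjusted p = 0.0686 with an estimated correlation), and 6 were higher and 1 lower when adjusted over the list alone. CXCL8 (0.84, adjusted p = 0.22), CXCL1 (0.50, adjusted p = 0.579) and RIPK2 (0.14, adjusted p = 0.794) did not pass. Of 33 interferon-stimulated genes 3 were higher in wt cells, OAS3 (1.56), IFIT3 (0.86) and IFITM1 (0.71) (camera adjusted p = 0.00527; adjusted p = 0.0834 with an estimated correlation and 0.085 with replicates 2 and 3 alone). On ranks the call of interferon-stimulated genes held (adjusted p = 0.0274) and that of NF-kB target genes did not (adjusted p = 0.0854).

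TGF-beta and matrix genes were higher in wt than in mock cells, with 6 of 21 past the threshold and 8 when adjusted over the list alone (camera adjusted p = 3.44e-08). They included ID1 (2.16) and ID3 (2.16), targets of bone morphogenetic proteins, SMAD7 (1.38) and the fibronectin gene FN1 (1.08). G2/M cell cycle genes were higher on balance (3 of 25 higher, BUB1 0.65, AURKA 0.42 and CENPF 0.40, and 1 lower, CENPE -0.73; 6 higher and 1 lower when adjusted over the list alone; camera adjusted p = 6.72e-05). p53 target genes were lower (3 of 17, SESN1 -0.82, FAS -0.53 and GADD45A -0.51; 4 when adjusted over the list alone; camera adjusted p = 0.000758). These 3 calls held with an estimated correlation and on ranks.

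The remaining list calls for wt against mock cells held neither with an estimated correlation nor on ranks. G1/S cell cycle genes were lower (4 of 25, GINS2 -1.86, CDT1 -1.27, CCNE2 -0.51 and MCM4 -0.41; 7 lower and 1 higher when adjusted over the list alone; camera adjusted p = 0.00109; adjusted p = 0.0599 with an estimated correlation). GINS2 and CDT1 lie on chromosome 16 and CCNE2 and MCM4 on chromosome 8. Cholesterol and fatty acid synthesis genes were lower (5 of 22, SQLE -0.99, IDI1 -0.49, ACAT2 -0.45, MSMO1 -0.43 and EBP -0.36; 6 lower and 1 higher when adjusted over the list alone; camera adjusted p = 0.026; adjusted p = 0.294 with an estimated correlation). HEK293 lineage markers were higher (5 of 19, ENO2 0.97, VIM 0.85, INA 0.61, NEFL 0.59 and KRT18 0.38; 6 when adjusted over the list alone; camera adjusted p = 0.00787; adjusted p = 0.196 with an estimated correlation).

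Before MDP the L1007fsinsC line was closer to the mock line, with 39 genes past the threshold, 15 higher and 24 lower, and 18 at least 2-fold. CYP7B1, an oxysterol hydroxylase, was at 4.0 ± 1.35 in L1007fsinsC cells and 443.3 ± 119 in mock cells (log2 -4.49). Since 4.0 lies below the offset of 16 added before taking logs, the offset sets the size of this difference, which was -6.48 with a pseudocount of 1 and -2.87 with 64, past the threshold in both. IFI16, an interferon-induced sensor of DNA, was lower too (-2.02; 54.2 ± 18.1 against 268.5 ± 78.4), as were the secreted matrix gene CTHRC1 (-2.43), PLEK2 (-2.24), the NAD synthesis gene NAPRT (-1.68), DUXAP10 (-1.66), CHMP4C (-1.54), PLAGL1 (-1.52), TUSC1 (-1.46) and VPS28 (-1.21), a gene of endosomal sorting. LRRN1 (2.57), LOC101929538 (2.11), IQCJ-SCHIP1-AS1 (1.83), FAM66C (1.79), APELA (1.40), TCEAL7 (1.27; 2224 ± 429 against 905.3 ± 78.1), ASB9 (1.12), the secreted regulator CCN3 (1.10; 2545 ± 152 against 1184 ± 160), VGLL3 (0.97) and the adhesion gene PCDH19 (0.97) were higher. CYP7B1, CTHRC1, NAPRT, CHMP4C, VPS28 and CCN3 lie on chromosome 8, which held 17 of the 24 lower genes. The offset also sets the sizes for LOC101929538 (mock mean 10.6; 3.17 and 1.12 with pseudocounts of 1 and 64) and APELA (mock mean 7.37; 2.51 and 0.62).

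The SE of these 20 genes ranged from 0.12 for CCN3 to 0.43 for LRRN1, and their adjusted p from 2.36e-07 for CYP7B1 to 0.037 for APELA. Heat shock genes were lower as a group: 0 of 16 passed over all genes, 4 did when adjusted over the list alone (DNAJA1, HSPH1, HSPB1 and STIP1), 0 of 16 were above 0, and the median was -0.24 (camera adjusted p = 4.05e-08). That call held with an estimated correlation and on ranks. G2/M cell cycle genes (0 of 25; camera adjusted p = 0.0873) and cholesterol and fatty acid synthesis genes (1 of 22, SQLE, lower; camera adjusted p = 0.185) were not called. With the batch block both were called as lower (adjusted p = 0.0206 and 0.0236), and G2/M genes also with replicates 2 and 3 alone (adjusted p = 0.0344). At an unadjusted p under 0.05 there were 1377 genes. The count of 39 was 132 with the batch block, including all 39, 11 with replicates 2 and 3 alone, 9 of them shared, 91 when dim genes were left out, 73 with the trend and robust options, 1 in a fit to the compared groups alone and 24 without mock 0 h replicate 1. Of the 20 named genes, 7 lost their call without at least 1 of the 6 arrays.

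Those 7 kept their direction, which is built in, since genes were named only if their replicates did not overlap. Their log2 values without the arrays that ended the call were as follows. APELA (1.28 to 1.50) was lost without any array except L1007fsinsC replicate 2, FAM66C (1.58 to 1.86) without any except L1007fsinsC replicate 1, and PLEK2 (-2.30 to -1.84) without any except L1007fsinsC replicate 3. LRRN1 (2.38 to 2.47) was lost without L1007fsinsC replicate 2 or 3 or mock replicate 3. LOC101929538 (2.00 to 2.08) was lost without L1007fsinsC replicate 1 or mock replicate 1 or 2. NAPRT (-1.74 to -1.25) was lost without L1007fsinsC replicate 2 or mock replicate 1 or 3. VGLL3 (0.85 to 0.89) was lost without L1007fsinsC replicate 1 or mock replicate 2. With replicates 2 and 3 alone 13 of the 20 did not pass, among them CCN3 (1.03) and CTHRC1 (-2.12), while CYP7B1, IFI16, DUXAP10, TUSC1, VPS28, LRRN1 and VGLL3 did.

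The lines with wild-type and variant NOD2 differed before MDP in 883 genes, 407 higher and 476 lower in wt cells, and 248 of them differed at least 2-fold. SOX11 (4.95), CYP7B1 (4.79, or 6.78 and 3.15 with pseudocounts of 1 and 64; 548.8 ± 140 in wt cells against 4.0 ± 1.35), IFI16 (4.24; 1296 ± 238 against 54.2 ± 18.1) and BMP2 (4.22) were higher in wt cells. So were AKR1C3 (3.03) and AKR1C2 (2.86), steroid-metabolising reductases, PLEK2 (3.03), the adhesion gene LSAMP (2.64), EDNRB (2.60) and ID3 (2.55; 3254 ± 588 against 573.5 ± 262). ZNF83 (-5.49; 14.6 ± 17.9 against 1231 ± 92.1), MGST1 (-4.16; 312.1 ± 98.1 against 5676 ± 332), PABPC4L (-3.39), ZKSCAN7 (-3.38), MAP7D2 (-3.38), ZNF677 (-3.37), ZNF257 (-3.25), BOLA1 (-3.06), the retinoic acid-forming enzyme gene ALDH1A1 (-3.04) and ZNF91 (-3.01) were lower. Means below the offset of 16 also set the sizes for ZNF83 (-6.95 and -4.06 with pseudocounts of 1 and 64), ZKSCAN7 (wt mean 8.33; -4.82 and -2.05), ZNF257 (wt mean 10.2; -4.49 and -1.99) and AKR1C3 (L1007fsinsC mean 13.6; 4.13 and 1.87). The adjusted p of these 20 genes ranged from 1.32e-11 for MGST1 to 0.00601 for LSAMP and the SE from 0.18 for ZNF91 to 0.65 for BMP2. At an unadjusted p under 0.05 there were 2894 genes. The count of 883 was 1522 with the batch block, including all 883, 577 with replicates 2 and 3 alone, 448 of them shared, 529 with the mean over all probe sets of a gene and 86 in a fit to the compared groups alone. With replicates 2 and 3 alone AKR1C3 (2.68) and LSAMP (2.28) did not pass.

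NFKBIA (1.49, adjusted p = 0.000196), IER3 (1.11, adjusted p = 0.000292) and TNFRSF9 (0.98, adjusted p = 0.0236) were higher in wt than in L1007fsinsC cells at 0 h, and TNFAIP3 (0.26, adjusted p = 0.52) did not pass. These were 3 of 23 NF-kB target genes, with 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0384; adjusted p = 0.261 with an estimated correlation, 0.185 with replicates 2 and 3 alone, 0.156 on ranks and 0.0636 with dim genes left out). L1007fsinsC and mock cells did not differ in NFKBIA (-0.04), TNFAIP3 (0.44, adjusted p = 0.509) or CXCL8 (0.59, adjusted p = 0.806) by this test.

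G2/M cell cycle genes were higher in wt than in L1007fsinsC cells (7 of 25, among them BUB1 0.91, AURKA 0.52 and CENPF 0.52; 11 higher and 1 lower when adjusted over the list alone; camera adjusted p = 7.09e-08), a call that held with an estimated correlation and on ranks. The following calls held with neither. TGF-beta and matrix genes were higher (7 of 21, among them ID3 2.55, ID1 2.43 and FN1 1.22; 7 when adjusted over the list alone; camera adjusted p = 0.000384; adjusted p = 0.091 with an estimated correlation). HEK293 lineage markers were higher (2 of 19, VIM 0.61 and KRT18 0.43; 6 when adjusted over the list alone; camera adjusted p = 0.0256; adjusted p = 0.261 with an estimated correlation). Heat shock genes were higher (2 of 16, HSPB1 1.04 and HSPE1 0.38; 2 when adjusted over the list alone; camera adjusted p = 0.0346; adjusted p = 0.41 with an estimated correlation).

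Lower in wt than in L1007fsinsC cells were genes of the unfolded protein and amino acid stress response (4 of 27, HERPUD1 -0.79, TRIB3 -0.58, XBP1 -0.47 and MANF -0.37; 6 lower and 1 higher when adjusted over the list alone; camera adjusted p = 0.00714; adjusted p = 0.212 with an estimated correlation and 0.165 with replicates 2 and 3 alone). G1/S cell cycle genes were lower (3 of 25, GINS2 -1.82, CDT1 -1.30 and CCNE2 -0.41; 3 when adjusted over the list alone; camera adjusted p = 0.00421; adjusted p = 0.091 with an estimated correlation). GINS2 and CDT1 lie on chromosome 16, whose median was -0.38 in this comparison. p53 target genes were lower (2 of 17, SESN1 -0.72 and GADD45A -0.66; 3 when adjusted over the list alone; camera adjusted p = 0.0052; adjusted p = 0.0686 with an estimated correlation). Among these, the calls of the stress response list and p53 target genes held on ranks (adjusted p = 0.0363 and 0.025) and that of G1/S genes did not (adjusted p = 0.102). Over all 15 comparisons 29 of 315 list tests were called, 14 with an estimated correlation, all among the 29.

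Most differences between lines kept their direction under MDP, in comparisons added after seeing the data. Of the 738 genes that differed between wt and mock cells at 0 h, 720 had the same sign at 2 h and 723 at 6 h, and 505 and 482 were called again. For the 39 of L1007fsinsC against mock cells these were 38 and 38, with 22 and 23 called again, and for the 883 of wt against L1007fsinsC cells they were 865 and 865, with 575 and 581 called again. Of the genes named as higher in L1007fsinsC than in mock cells at 0 h, FAM66C gave -0.08 at 2 h and -0.52 at 6 h (adjusted p = 0.994 and 0.826), LOC101929538 0.21 and 0.09 (adjusted p = 0.981 and 0.998), APELA 0.36 and 0.49 (adjusted p = 0.889 and 0.778) and IQCJ-SCHIP1-AS1 0.76 and 0.45 (adjusted p = 0.528 and 0.828). NAPRT, named as lower, gave -0.70 and -0.92 (adjusted p = 0.582 and 0.324). A change of these differences with time did not pass for any of the 5 genes.

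Many of the genes lower in wt cells lie on chromosome 16, a grouping examined after seeing the data. The median log2 difference of its 523 brighter genes was -0.40 against mock cells and -0.38 against L1007fsinsC cells, and 87.0% of these genes were lower in wt than in mock cells. Of 825 chromosome 16 genes, 125 were called lower in wt than in mock cells and 8 higher (Fisher's exact test for lower calls, adjusted p = 9.67e-66). Over the 41 neighbouring brighter genes from GINS2 to DBNDD1 the median was -1.14. On chromosome 8 the median was -0.35 for wt and -0.27 for L1007fsinsC cells, each against mock cells. For wt against L1007fsinsC cells it was -0.06, so much of that difference lay in the mock line. Against mock cells, 86 of its 716 genes were called lower in wt and 17 in L1007fsinsC cells. Chromosomes 2, 7 and 14 were shifted the other way. On chromosome 2, 138 of 1309 genes were called higher in wt than in L1007fsinsC cells (Fisher's exact test for higher calls, adjusted p = 5.8e-60; median 0.17), on chromosome 7 58 of 933 (adjusted p = 1.08e-12; median 0.13) and on chromosome 14 53 of 611 (adjusted p = 1.62e-17; median 0.26). Against mock cells the medians of these 3 chromosomes were 0.10, 0.12 and 0.18 for wt cells and -0.08, 0.01 and -0.08 for L1007fsinsC cells. Genes of a chromosome are not independent replicates, so the Fisher tests overstate the evidence. A permutation test of whole arrays, over all times, gave an adjusted p = 0.000158 in each comparison for which a Fisher test is given. Its unadjusted p of 4.11e-05 there is the smallest this test can give, so it does not rank the shifts. Chromosome 8 in wt against L1007fsinsC cells, at -0.06, gave the same values. The permuted arrays come from 1 line per construct, so the test concerns these lines and not the constructs. A smaller shift down was seen in wt cells on chromosome 6 against mock cells (-0.15). On chromosome 3 the median was -0.15 for wt against L1007fsinsC cells. Against mock cells it was 0.10 for L1007fsinsC cells and -0.06 for wt cells, so much of that difference lay in the L1007fsinsC line. Without the genes of chromosomes with shifted medians 239 genes differed between wt and mock cells, 17 between L1007fsinsC and mock cells, and 314 between wt and L1007fsinsC cells. No list test was run without these genes, so the part of chromosome shifts in the list calls at 0 h is untested.

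**Figure D4:**
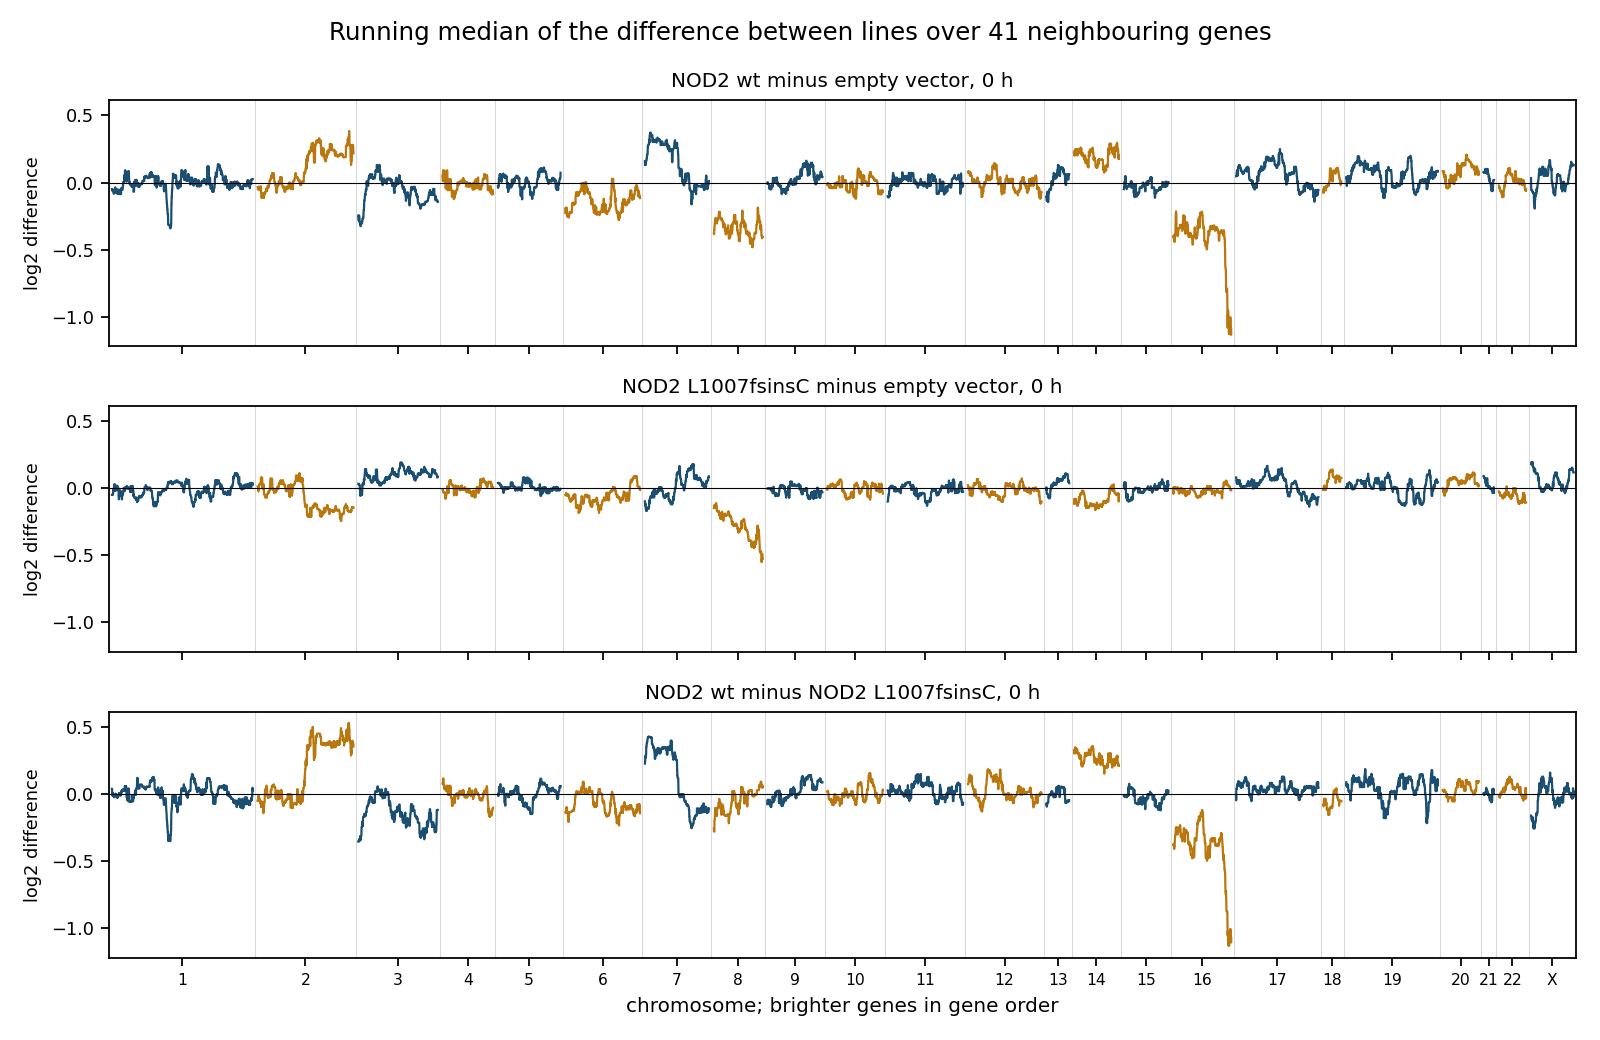
Running median of the log2 difference between lines at 0 h over 41 neighbouring brighter genes, in gene order along chromosomes 1 to 22 and X, for the 3 pairs of lines. Chromosome 16 lies below 0 where the wt line is compared, and chromosome 8 lies below 0 against mock cells in both other lines.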

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

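The tests on ITGAM the sorting of the splits by whether they mixed the wt arrays, and the splits within replicate numbers were chosen after the result was seen, and the splits of the samples were planned.

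These results stood out because the response to MDP differed between lines in a test of the difference itself. Against mock cells, the 2 h response of wt cells was larger by 3.27 for CXCL8, 1.74 for ITGAM and 1.50 for TNFAIP3 on the log2 scale. Against L1007fsinsC cells it was larger by 2.49 for APELA (4.78 and 1.08 with pseudocounts of 1 and 64, since 2 of its means lie below the offset of 16), 3.17 for CXCL1, 3.01 for CXCL8, 1.45 for IER3, 2.19 for ITGAM and 1.68 for TNFAIP3. Among the lists, the mean difference against mock cells was 0.35 for NF-kB target genes, 0.46 for cytokines and chemokines, 0.32 for negative regulators and 0.20 for immediate early genes. Against L1007fsinsC cells it was 0.26 for NF-kB target genes, 0.45 for cytokines and chemokines and 0.37 for negative regulators. Groups of 3 arrays were not tested for single arrays far from the others.

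Other splits of the 12 arrays were compared with the real groups of the interactions. For wt against L1007fsinsC cells at 2 h, 1 of 100 splits, the real one, gave as many as 6 genes. The highest other gave 4. This share concerns the grouping of the 12 arrays as a whole and cannot exclude chance for the difference between the lines. Of the other splits, 90 mixed the wt arrays and gave at most 2, so they test the wt response. The 9 that kept the wt arrays in their real groups gave at most 4, and are too few to test the L1007fsinsC arrays by themselves. For wt against mock cells at 2 h, 10 of 100 splits gave 3 or more genes and the highest other gave 8, so chance cannot be excluded for that count. All 9 others with 3 or more genes kept the wt arrays in their real groups, so they held the real wt response, and the 89 splits that mixed the wt arrays gave at most 2. The share of 10 in 100 therefore says little of whether the wt arrays were grouped by chance. These splits ignore the hybridization batch. When 0 h and 2 h arrays were exchanged only within a line and replicate number, which keeps the batch balanced, 1 of 32 splits, the real one, gave 6 genes for wt against L1007fsinsC cells, with 4 in the highest other. For wt against mock cells 8 of 32 gave 3 or more, all with the wt arrays in their real groups, with 8 in the highest other and at most 1 in the 24 that mixed them. For the 4 interactions with 0 genes, all 100 splits gave as many, and the highest other gave 3 for wt against mock cells at 6 h, 3 and 1 for L1007fsinsC against mock cells at 2 h and 6 h, and 2 for wt against L1007fsinsC cells at 6 h.

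For the other comparisons the 10 splits of 6 arrays are too few for a share under 0.05. The real and highest other values were 6 and 1 for wt cells at 2 h, 0 and 1 for wt cells at 6 h, 0 and 2 for L1007fsinsC cells at 2 h, 0 and 0 at 6 h, 0 and 1 for mock cells at 2 h, and 0 and 0 at 6 h. They were 738 and 2 for wt against mock cells at 0 h, 39 and 0 for L1007fsinsC against mock cells, and 883 and 2 for wt against L1007fsinsC cells. The number of splits with as many genes as the real one was 1 for wt cells at 2 h and for each of the 3 comparisons at 0 h, and 10 for the rest.

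Of the 6 genes called in wt cells at 2 h, ITGAM alone stood in none of the lists of response genes, and its list was leukocyte markers. RNA of leukocytes is argued against, because the other 17 leukocyte markers had a median log2 change of -0.0087 (SD 0.25) with 0 called. Low values on the wt 0 h arrays may account for most of the change: 70.8% of it was the wt 0 h mean lying below the other lines at 0 h, with wt 0 h arrays at 45.5 to 90.4 and the 18 arrays of the other lines at 91.3 to 216.9. The wt 2 h arrays, at 239.5 to 245.5, were nonetheless above all of these. A truly lower level in the wt line before MDP would give the same share, so the share cannot separate these 2 cases. ITGAM lies on chromosome 16, whose genes were lower in that line. Whether the probe set follows the ITGAM transcript cannot be told apart from a real change, since the other probe set (-0.41) has a low mean signal of 64.4, as the first has in wt cells at 0 h (65.2), and a response to MDP stays open.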

How the results depend on the processing

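The batch block, the fits to replicates 2 and 3 alone, the fit to replicate 1 alone and the fits without shifted chromosomes were chosen after seeing the data. None of the 75 named and passing results changed direction. This is in part built in, since such genes were named only if their replicates did not overlap. Several alternatives, such as leaving out an array, could then not reverse a simple difference between groups. Of their 1349 values under the alternatives, 1182 stayed past the threshold and 167 did not, and 29 results passed in every setting. Of 1664 values of the 86 named results that did not pass, 25 passed, all without a change of sign. Changes of sign among values that passed in neither fit were not counted. No scaling moved the median of all genes in a comparison by more than 0.0863. The cause was not tested except where fewer genes or arrays were used.

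Over all genes, residuals of arrays with the same replicate number correlated at -0.00662 to 0.131 over 108 pairs (mean 0.0583, against -0.0291 for other numbers). Over brighter genes they correlated at 0.0338 to 0.413 (mean 0.199, against -0.0982). In some comparisons, among them the 2 h responses of wt and L1007fsinsC cells, every pair exceeded 0.1 over brighter genes. As this did not hold for every pair in either set of genes, the arrays were not treated as pairs. Over brighter genes every pair was nonetheless above 0, and the main fit leaves this shared variation in its residuals. Of 27 arrays, 25 had their highest mean correlation with the arrays of their own number in other groups. The means given for other numbers follow from those for the same number, since the residuals of a group cancel. A replicate block gave 1371 genes for wt against mock cells at 0 h, 143 for L1007fsinsC against mock, 1573 for wt against L1007fsinsC, 5 for wt against mock at 2 h, 1 for mock cells at 6 h, and 7 for wt cells at 2 h with JUN added. With it, immediate early genes were called for wt against L1007fsinsC at 2 h (adjusted p = 0.0122), and G2/M genes (adjusted p = 0.0237) and cholesterol and fatty acid synthesis genes (adjusted p = 0.0232) for L1007fsinsC against mock at 0 h. The batch block gave 1313, 132, 1522, 5 and 1 for these, and 1 for mock cells at 2 h. Replicates 2 and 3 alone gave 436, 11 and 577 at 0 h, 11 and 2 for wt cells at 2 h and 6 h, 1 for L1007fsinsC cells at 6 h, 0 for wt against mock at 2 h, 5 for L1007fsinsC against mock at 6 h and 3 for wt against L1007fsinsC at 6 h. The 9 replicate 1 arrays alone, fitted with line plus time and so averaged over the 3 times, gave 181, 0 and 278 genes for the differences between lines. Of the genes called at 0 h, 737 of the 738, 38 of the 39 and 880 of the 883 had the same sign there, and 135, 0 and 214 also passed. The agreement in sign is in part built in, since the replicate 1 arrays at 0 h helped to call these genes. The compared groups alone gave 86, 1 and 86 at 0 h, 1 for wt cells at 2 h, 0 for wt against mock and for wt against L1007fsinsC at 2 h, and 1 and 2 for wt and L1007fsinsC against mock at 6 h. The mean over probe sets gave 411 for wt against mock and 529 for wt against L1007fsinsC at 0 h. Leaving out dim genes gave 91 for L1007fsinsC against mock at 0 h and 3 for wt against L1007fsinsC at 2 h, and the trend and robust options gave 73 for the former. Without shifted chromosomes the 0 h counts were 239, 17 and 314. A pseudocount of 1 gave 2 for wt cells at 6 h, 3 for mock cells at 2 h and 1 at 6 h, and quantile normalization and median centring each gave 1 for mock cells at 6 h. Leaving out dim genes added interferon-stimulated genes for wt against L1007fsinsC at 0 h (adjusted p = 0.025). Of the list calls, 14 held with an estimated correlation and 10 with ranks, and all 7 calls for differences between lines in the response were lost with ranks. The count of shared response calls of wt and L1007fsinsC cells was 0 in the 4 alternatives run, and could be nothing else in those where L1007fsinsC cells had 0 calls.

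Leaving out 1 array in turn gave 6 to 11 genes for wt cells at 2 h and 0 to 1 at 6 h, 0 to 2 and 0 to 3 for L1007fsinsC cells, 0 to 5 and 0 to 2 for mock cells, 0 to 6 and 0 to 1 for wt against mock, 0 to 1 and 0 to 1 for L1007fsinsC against mock, and 2 to 8 and 0 to 1 for wt against L1007fsinsC. At 0 h it gave 449 to 508 for wt against mock, 24 to 38 for L1007fsinsC against mock and 590 to 705 for wt against L1007fsinsC. Among named genes that did not pass, those with a mean below the offset of 16 also have sizes set by it. With pseudocounts of 1 and 64, PROX2 gave 3.10 and 1.15 for wt cells at 6 h, and APELA -1.98 and -0.56 at 2 h, LOC101929538 -2.88 and -1.04 at 6 h and FGF3 2.31 and 0.79 at 6 h for L1007fsinsC cells. In mock cells LINC01813 gave -3.88 and -1.11 and LINC00950 -1.75 and -0.43 at 2 h, and HTR2C 3.76 and 1.44 and FAM99B -3.03 and -1.31 at 6 h. At 6 h AKAIN1 gave -4.68 and -1.43 for L1007fsinsC against mock cells, and ZNRF2P1 5.43 and 1.94 for wt against L1007fsinsC cells. Dim signal limits what can be seen: the median SE was 0.29 over all genes and 0.19 over brighter genes.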

Other observations

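The tests on chromosome 16 and on replicate 1, and the comparisons of lines at 2 h and 6 h, were chosen after the results were seen.

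Several gene groups showed no call in any of the 15 comparisons. The smallest camera adjusted p was 0.412 for NOD2 signalling components (29 measured), 0.203 for FOXO and growth factor withdrawal genes (24), 0.44 for hypoxia and glycolysis genes (24), 0.471 for autophagy genes (23), 0.125 for oxidative stress (NRF2) genes (18) and 0.579 for epithelial and antimicrobial defence genes (22). Leukocyte markers (18) gave 0.412 and fibroblast and endothelial markers (20) gave 0.429. The median signal was 123 for leukocyte markers, with 6 of 18 above the array median, and 99.6 for fibroblast and endothelial markers, with 7 of 20 above it. HEK293 lineage markers had a median signal of 737, with 15 of 19 above the array median.

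A lower level of chromosome 16 genes in the wt line may reflect fewer copies of that chromosome or of a part of it, as a hypothesis, since DNA was not measured. It predicts the same shift at every time. Of the brighter chromosome 16 genes, 86.0% were lower in wt than in mock cells at 2 h and 87.6% at 6 h. Any stable difference between the lines predicts this too, so it does not favour fewer copies. Of all 738 genes called at 0 h, 97.6% kept their sign at 2 h and 98.0% at 6 h. Scaling of the arrays, by 1 factor or by signal, is argued against as the whole cause, because chromosome 16 genes differed by -0.41 at the median from genes of other chromosomes with equal signal (10 bins, gaps of -0.51 to -0.08, the weakest in the dimmest bin). The gap between chromosome 16 and the other chromosomes was -0.38 at its weakest over the 3 replicate numbers. A hybridization batch that follows these numbers could not by itself part the lines, since each number holds wt and mock arrays alike. A batch that parts the lines within each number was not tested. Regulation that acts along the chromosome without a change of copies stays open, and with 1 line per construct a difference due to the construct is untested.

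Replicate 1 arrays of every group stood apart from replicates 2 and 3. Their spiked-in bioB and bioC transcripts were at 11.93 ± 0.07 (9 arrays) against 10.90 ± 0.22 (18 arrays), a log2 difference of 1.04, which is consistent with a separate hybridization batch. RNA degradation cannot be told apart as a part of it: the log2 ratio of the 3' to the 5' ACTB probe set differed by -0.15, with replicate 1 lower at 0.53 ± 0.06 against 0.68 ± 0.11, and that of GAPDH by -0.13 (-0.02 ± 0.05 against 0.10 ± 0.06). Both exceed the spread among replicates 2 and 3. No biological explanation was tested, since each group holds 1 array of each replicate number.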
